A study of Mus musculus with 12 samples.

How the data were processed

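Gene expression was measured in mouse epiblast stem cells, pluripotent cells that resemble the epiblast of the embryo after implantation. Per the labels' protocols, the cells were grown in N2B27 medium with bFGF and Activin A, total RNA was extracted with Trizol, and biotin-labelled cRNA was prepared. The arrays were Affymetrix mouse 430 2.0 arrays, per the platform annotation. The 12 arrays fell into 4 groups of 3 biological replicates by the labels: diploid EpiSC-1, diploid EpiSC-2, haploid EpiSC-1 and haploid EpiSC-2. EpiSC-1 and EpiSC-2 were read as separate cell lines of each ploidy. The diploid cells were labelled B6D2F1 and the haploid cells 129Sv, so every difference between the ploidies is also a difference between strains.

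The deposited values were MAS5 signal intensities on a linear scale, per the submitters' processing notes, with the version not given in the sources used here. The trimmed mean of each array, computed here without the highest and lowest 2% of probe sets, was 499.8, which places the scaling target at 500. No value was at or below 0, and the lowest was 0.0453. The table held 45101 probe sets, of which 64 were Affymetrix controls and were dropped. Of the others, 34945 were paired with 1 gene symbol in the platform annotation, 932 with several and 9160 with none. Probe sets with several symbols or none were left out of the gene tests. Chromosomes were taken from a table of the GRCm38.p6 assembly through the Entrez identifier, which matched for 34741 probe sets, and no coordinates were used. The probe set with the highest mean log2 signal stood for each of 18194 genes. Genes whose mean log2 signal was at or above 5.97, the median of all probe-set means (a signal of 62.6), were tested. This left 11105 genes. Values were used as log2 signals without a pseudocount and without a further normalization. Detection calls and scan dates were not used here, so folds against a group near the background are uncertain in size, and the number of arrays limits the precision.

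Haploid and diploid cells were compared with limma 3.58.1 in R 4.3.3. The 4 lines entered as a random block through duplicateCorrelation (statmod 1.5.0), with empirical Bayes moderation and an intensity trend. The correlation between arrays of a line was 0.806. The lines of each ploidy were compared in a limma fit of 4 group means over all 12 arrays. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Gene lists and whole chromosomes were tested with limma's cameraPR, which sets the moderated statistics of a list against those of all other genes, with a preset correlation of 0.01 and at least 5 tested genes. Each such test was repeated with a correlation estimated from the residuals. Tests were two-sided.

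Before the data were examined, 37 gene lists were fixed. Of their 847 entries, 760 matched a gene on the array. The lists of Y-linked and of two-cell-like genes had too few tested genes, which left 35. These were core pluripotency, naive pluripotency, primed epiblast, primitive streak and mesoderm, definitive endoderm, primitive and visceral endoderm, neuroectoderm, trophoblast, fibroblast feeder markers, germline genes, maternally and paternally expressed imprinted genes, X-inactivation escape and centre, p53 targets, G1/S and DNA replication, G2/M and mitosis, DNA damage response and repair, apoptosis regulators, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, MHC class I and antigen presentation, interferon-stimulated genes, Nodal and Activin targets, FGF and ERK targets, Wnt targets, BMP targets, DNA methylation and heterochromatin, Polycomb and Trithorax, cholesterol synthesis, unfolded protein response, hypoxia, epithelial genes, mesenchymal genes, and loci with known strain copy-number or null alleles. The list tests between the haploid lines were added after the data had been seen.

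Genes to name were also fixed beforehand. They were the 12 highest and 12 lowest log2 fold changes between the ploidies and the 5 highest and 5 lowest between the lines, among called genes whose arrays did not overlap. Up to 4 members of each list with the lowest p, the 3 genes with the lowest p on each called chromosome, and Pou5f1, Nanog, Sox2, Zfp42, Esrrb, Klf4, Dppa3, Fgf5, Otx2, Dnmt3b, T, Xist and Trp53 were added to these. No probe set was paired with T or Trp53 alone. Zfp42, Esrrb and Dppa3 lay under the signal filter, so only their signals are given.

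Each step was tested on simulated data of the 11105 genes with 200 changed genes, drawn with the spread seen within the lines. The spread seen between the lines was added for the haploid against diploid and list tests. It was not added for the comparisons between lines of a ploidy. In the haploid against diploid comparison, 67% of 2-fold and 86% of 4-fold changes were recovered, but 239 of the 392 calls were unchanged genes. Without the line block 5203 of 5402 calls were unchanged genes, and with line means as units there were 0 calls. Between haploid lines 91% and 97% were recovered, with 10 unchanged genes among 198 calls. Between diploid lines the shares were 91% and 99%, with 4 unchanged genes among 194 calls. The list test gave an adjusted p of 2.57e-30 for a shifted list and called 0 of 36 unshifted ones. Genes were simulated independently and the lists drawn at random, so this does not show how often lists of correlated genes are called wrongly. Alternatives covered the normalization between arrays, the signal filter, a pseudocount of 19.4, the choice of probe set, the intensity trend, the replicate number as a block, the line as a block, each line or array left out, and a 2-fold threshold. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.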

Results

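Transcripts of 4 mouse epiblast stem cell (EpiSC) lines were measured on 12 arrays, with 3 biological replicates of each of 2 diploid lines (strain B6D2F1) and 2 haploid lines (strain 129Sv). Haploid cells carry a single chromosome set. The median signal of an array lay between 63.6 and 76.5. Replicates of a line correlated at 0.989 to 0.992 over the 11105 tested genes on the log2 scale. The diploid lines correlated with each other at 0.950 to 0.952 and the haploid lines at 0.951 to 0.954, while arrays of different ploidy correlated at 0.856 to 0.909. The first principal component held 63.3% of the variance and separated the ploidies, and the second held 16.2% and separated the lines of each ploidy. The median standard deviation of a gene between replicates was 0.0867 to 0.0980 on the log2 scale.

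**Figure D1:**
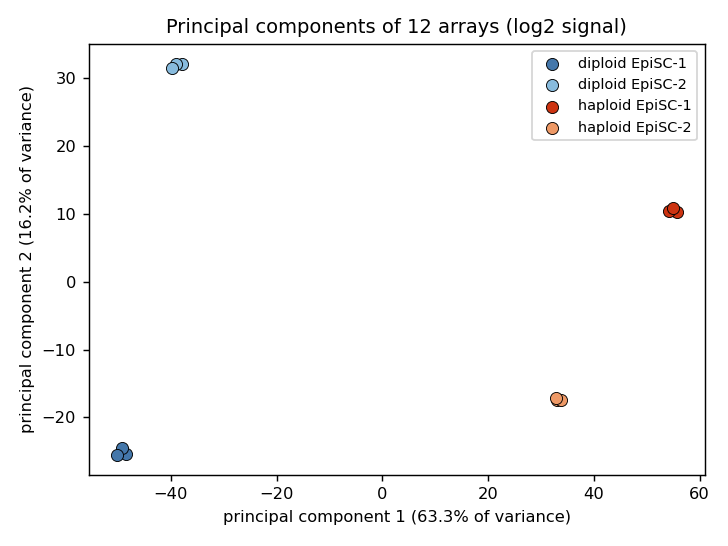
Scores of the 12 arrays on the first (horizontal axis, 63.3% of variance) and second (vertical axis, 16.2% of variance) principal components of the log2 signals, with 1 point per array coloured by line. The haploid arrays lie on the right and the diploid arrays on the left, and the 3 replicates of each line lie together.

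The first comparison asked how haploid EpiSCs differ in expression from diploid EpiSCs. The lists of fibroblast feeder markers and of mesenchymal genes were higher in the haploid lines, and the list of epithelial genes was lower. Col3a1, a fibrillar collagen gene (Entrez 12825, chromosome 1), rose by 6.56 ± 0.37 (log2, SE, 6 arrays from 2 lines of each ploidy, adjusted p = 2.64e-08). Over the alternatives its adjusted p was 0.00672 at the highest. With 2 lines of each ploidy, p values as small as in the main fit are uncertain. Its mean signals were 51.8 and 130 in the diploid lines and 8147 and 7309 in the haploid lines. Paternally expressed imprinted genes and targets of BMP signalling were higher as groups. Targets of p53 were lower in the preset test (adjusted p = 0.0504 with an estimated correlation). The pluripotency factor Sox2 rose by 1.85 ± 0.17 (adjusted p = 2.81e-06, and 0.0215 at the highest over the alternatives). Pou5f1, which encodes Oct4, fell by 0.77 ± 0.20 on the log2 scale (adjusted p = 0.013, and 0.156 with line means as the units).

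Of 11105 genes, 1913 passed the threshold, 1076 (56.2%) higher and 837 lower in haploid cells. With arrays centred on their medians, which shifted the median of all genes by -0.12, 812 (42.8%) were higher and 1086 lower. At least 2-fold changes were found in 652 of the higher and 316 of the lower genes. Strain and ploidy were the same division of the arrays. With line means as the units, 2 against 2, 325 genes passed, and of the genes named here the calls of Insig1, Grb10, L1td1, Pou5f1, Cdh1, Dppa5a, Stat3, Dnmt3b, Sox3, Col4a1, Lamb1, Rian, Nuf2, Atr, Chek2, Spry1, Fos, Id3, Tet1, Klf4, Otx2, Hoxa11 and Hoxd13 were lost. In the simulation the fit with the line block called mostly unchanged genes, 239 of 392, while line means gave 0 calls.

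The largest increases included Pmaip1, a BH3-only promoter of cell death, at 8.81 ± 1.35 (adjusted p = 3.33e-04), with diploid signals of 6.61 and 9.77 against 2968 and 2943. With a pseudocount its increase was 6.77. Rps4l, a ribosomal protein gene, rose by 8.09, the cadherin gene Cdh11 by 7.32, the zinc finger gene Zic1 by 7.26, Emp1 by 7.21 and the guanylate-binding protein gene Gbp2b by 6.79. Insig1, a regulator of sterol synthesis, rose by 7.09, with 4.34 to 9.83 over the alternatives and a difference of -5.50 between the diploid lines. Hoxa9 rose by 6.46, Smim3 by 6.40, Gstm5 by 6.29 and Megf10 by 6.17. The largest decreases were in Olig1, a neural transcription factor (-7.27 ± 1.29, adjusted p = 0.00106), the neuropeptide gene Npy (-6.64), the death receptor gene Eda2r (-5.32), Spon1 (-5.03) and the tight junction gene Ocln (-3.78). Grb10 followed at -3.55, 1700007K13Rik and Dcxr at -3.54, 3110045C21Rik at -3.33, the glutamine transporter gene Slc1a5 at -3.29, Spata5l1 at -3.07 and Galc at -3.06. Several of these genes lay near the background in 1 ploidy, where folds are uncertain in size.

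The list of fibroblast feeder markers had a median log2 fold change of 2.90 (adjusted p = 1.26e-16). Of its 26 tested genes, 21 rose and none fell, with 24 higher when adjusted over the list alone. Besides Col3a1, the collagen gene Col1a2 rose by 4.27, the smooth muscle actin gene Acta2 by 3.68 and the PDGF receptor gene Pdgfrb by 4.46. Both diploid lines expressed 12 of the 26 genes at or above the signal filter, and 5 of the 26 also stood in the mesenchymal list. That list had a median of 1.96 (adjusted p = 9.43e-13), with 13 of 19 genes higher and 0 lower, and 17 higher when adjusted over the list alone. Snai2, a repressor of epithelial genes, rose by 4.75, Tgfbi by 5.93 and the N-cadherin gene Cdh2 by 1.55. Epithelial genes had a median of -1.06 (adjusted p = 6.05e-09). Of 20, 11 fell and 0 rose, with 12 lower when adjusted over the list alone. Among them, the E-cadherin gene Cdh1 changed by -1.47, Epcam by -1.10 and the claudin gene Cldn7 by -2.37. These 3 lists passed the threshold with an estimated correlation too, with adjusted p values of 1.01e-05, 7.77e-04 and 1.01e-05. The ratio of 3' to 5' signal of the actin control probe sets also parted the ploidies, at 1.34 to 1.42 in haploid and 1.46 to 1.68 in diploid arrays, while that of Gapdh overlapped (0.821 to 0.938 over all arrays).

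**Figure D2:**
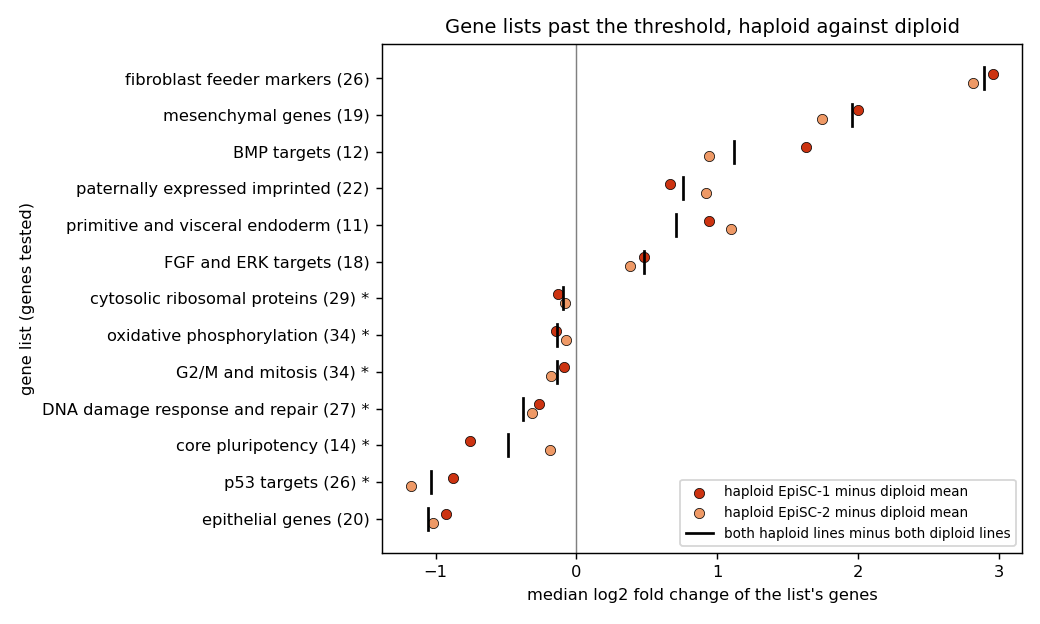
Median log2 fold change (horizontal axis) of each gene list that passed the threshold between haploid and diploid lines, with the number of tested genes in brackets. Black bars give both haploid against both diploid lines, points give each haploid line against the mean of the diploid lines, and an asterisk marks the 6 lists that did not pass with an estimated correlation; fibroblast and mesenchymal genes have the highest medians (2.90 and 1.96) and epithelial genes the lowest (-1.06).

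Imprinted genes are expressed from the maternal or the paternal allele alone. The paternally expressed list had a median of 0.76 (adjusted p = 1.10e-05, and 1.02e-05 with an estimated correlation). Of 22 genes, 11 rose and 1 fell (13 and 2 when adjusted over the list alone). The member that fell was Commd1 (-0.60, and -0.74 on its other tested probe set). Which allele a list member expressed was not measured. Mest rose by 2.80 ± 0.29 and Slc38a4 by 1.72. Ndn rose by 1.58, and its 4 other tested probe sets were at 1.48 to 1.70, while the mean of all its probe sets was at 0.69 (adjusted p = 0.171). Impact rose by 1.96 on its brightest probe set, but its other tested probe set was at -0.58 and the mean of its probe sets at 0.01 (adjusted p = 0.995). The maternally expressed list did not pass (median -0.22, adjusted p = 0.152), but 5 of its 20 genes fell and 0 rose (6 and 2 when adjusted over the list alone). Grb10, a growth inhibitor, changed by -3.55 ± 0.48 (adjusted p = 1.07e-04, and 0.0766 with line means), with a difference of 2.64 between the haploid lines. Phlda2 changed by -2.34 and Igf2r by -1.62. H13 also fell, by -0.78 on its brightest probe set, but its other tested probe sets were at -0.40 and 1.49. Rian was at -0.42 (adjusted p = 0.0398), but its call held in only 15 of 27 alternatives and was lost without any of 7 single arrays, and the mean of its probe sets was at -0.02 (adjusted p = 0.952).

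Among core pluripotency genes, 1 of 14 rose and 4 fell (1 and 5 when adjusted over the list alone), with a median of -0.48 (adjusted p = 0.0154). The call was not kept with an estimated correlation (adjusted p = 0.158). It was also lost without haploid EpiSC-1, without diploid EpiSC-1, with quantile normalization and with a stricter signal filter. Against the mean of the diploid lines, the list median was -0.76 in haploid EpiSC-1 and -0.19 in haploid EpiSC-2. Sox2 was the gene that rose. Tdgf1, the co-receptor of Nodal, changed by -1.07 and L1td1 by -0.74. Nanog was at -0.66 (adjusted p = 0.0879). The naive list did not pass (median 0.60, adjusted p = 0.785, 3 of 11 genes higher and 2 lower over all genes and over the list alone), nor did the primed epiblast list (median -0.27, adjusted p = 0.705, 3 of 21 higher and 4 lower, and 5 and 7 when adjusted over the list alone). In the naive list, Gbx2 rose by 2.41 and Dppa5a changed by -1.52. Stat3 rose by 1.32, but by 0.51 with the mean of its probe sets (adjusted p = 0.473). Klf4 rose by 1.47 (adjusted p = 0.0474). Its call was lost without single arrays, with adjusted p values up to 0.183 over all alternatives. In the primed list, the de novo DNA methyltransferase gene Dnmt3b changed by -1.27 (adjusted p = 0.00356, and 0.133 with line means), Sox3 by -1.52 (adjusted p = 0.122 with line means) and Lefty1 by 1.09. Signals of Zfp42 were 18.9 and 14.6 in the diploid and 87.7 and 107 in the haploid lines. Esrrb was at 55.0 and 76.8 against 52.0 and 62.3, and Dppa3 at 38.8 and 55.1 against 71.3 and 58.6.

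**Figure D3:**
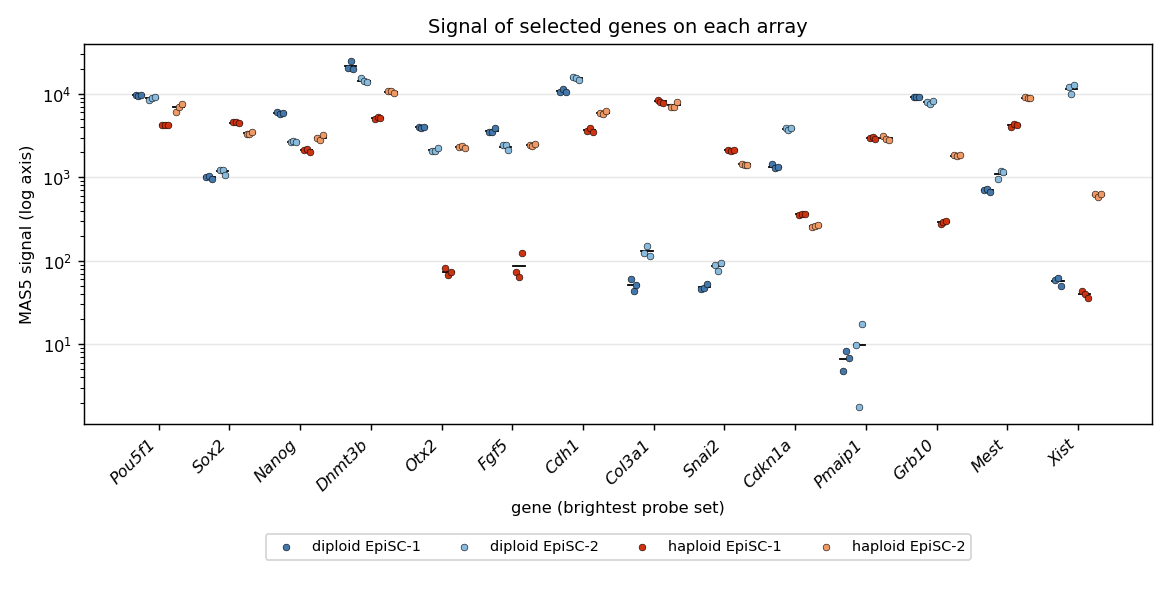
MAS5 signal (logarithmic vertical axis) of selected genes on each of the 12 arrays, with points for arrays, black bars for the mean of 3 replicates and colours for lines. Col3a1 and Snai2 lie higher and Cdh1 and Cdkn1a lower in both haploid lines, while Otx2 and Fgf5 are low in haploid EpiSC-1 alone (74.0 and 86.9).

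BMP targets had a median of 1.12 (adjusted p = 1.58e-05, and 0.0395 with an estimated correlation), with 6 of 12 genes higher and 0 lower (7 when adjusted over the list alone). Bmp4 itself rose by 3.14, and the inhibitors of differentiation Id1 and Id3 by 2.26 and 2.19. FGF and ERK targets had a median of 0.48 (adjusted p = 0.0118, and 0.00888 with an estimated correlation). Of 18, 7 rose and 0 fell (9 and 1 when adjusted over the list alone), among them the phosphatase gene Dusp4 (1.60), Spry1 (1.17) and Fos (1.43). Their call was lost without diploid EpiSC-1 (adjusted p = 0.0864). Primitive and visceral endoderm genes had a median of 0.71 (adjusted p = 0.00437, and 0.00445 with an estimated correlation), with 4 of 11 higher (5 when adjusted over the list alone). The members that rose were the basement membrane collagens Col4a1 (2.08) and Col4a2 (2.65), the laminin gene Lamb1 (0.46) and the endocytic adaptor gene Dab2 (1.78). With the mean of all probe sets the adjusted p of this list was 0.0600.

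Of 26 p53 targets, 13 fell and 3 rose, with the same counts when adjusted over the list alone (median -1.04, adjusted p = 1.84e-05). The adjusted p was 0.0504 with an estimated correlation. The cyclin gene Ccng1 changed by -3.05, the cell cycle inhibitor gene Cdkn1a by -2.89 ± 0.32, Zmat3 by -2.04 and the nuclease gene Aen by -1.68. Those that rose were Pmaip1 and the stress genes Gadd45a (1.27, with overlapping arrays) and Gadd45g (2.93), the last chosen after its values were seen. DNA damage response genes had a median of -0.38 (adjusted p = 6.21e-04), with 6 of 27 lower, including the checkpoint kinase genes Atr (-0.95) and Chek2 (-0.93), and 7 lower when adjusted over the list alone. This list had an adjusted p = 0.0962 with an estimated correlation. In 3 further lists, small median decreases passed the preset test only. G2/M genes had a median of -0.14 with 8 of 34 lower (adjusted p = 0.00341, and adjusted p = 0.180 with an estimated correlation), including the spindle genes Hmmr (-1.05) and Nuf2 (-1.06). Ribosomal protein genes had -0.09 with 3 of 29 lower (adjusted p = 0.0127, and adjusted p = 0.692 with an estimated correlation), and oxidative phosphorylation genes -0.13 with 5 of 34 lower (adjusted p = 0.0178, and adjusted p = 0.494 with an estimated correlation). In these 3 lists 0 genes rose, and the counts adjusted over the list alone were 8, 3 and 5.

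The remaining lists did not pass the threshold. Adjusted p values were 0.591 for primitive streak and mesoderm, 0.107 for definitive endoderm, 0.685 for neuroectoderm, 0.264 for trophoblast, 0.832 for germline genes, 0.519 for X-inactivation escape and centre, 0.648 for G1/S and DNA replication, 0.930 for apoptosis regulators and 0.914 for glycolysis. They were 0.171 for MHC class I and antigen presentation, 0.591 for interferon-stimulated genes, 0.908 for Nodal and Activin targets, 0.245 for Wnt targets, 0.946 for DNA methylation and heterochromatin, 0.401 for Polycomb and Trithorax, 0.106 for cholesterol synthesis, 0.946 for the unfolded protein response, 0.245 for hypoxia and 0.785 for loci with known strain alleles. Median, mean and test differed in sign for germline genes (median 0.54, mean -0.01, test upward), apoptosis regulators (0.07 and 0.41, downward), glycolysis (-0.02 and 0.01, downward) and cholesterol synthesis (-0.30 and 0.13, downward). Single members moved within these lists. The caudal homeobox gene Cdx2 rose by 5.77, the immunoproteasome gene Psmb9 changed by -2.27, the Wnt targets Apcdd1 and Nkd1 rose by 1.83 and 1.99, Bmi1 of the Polycomb group rose by 1.97 and Tet1 changed by -1.22. With the mean of all probe sets the calls of Tet1, Nkd1, Sox3, Dab2, Lamb1 and Atr were lost.

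Of 20 chromosomes, 4 passed the threshold. Chromosome 11 was lower in haploid cells (median -0.30, 31 of 917 genes higher and 182 lower, and 42 and 219 when adjusted over the list alone, adjusted p = 2.21e-08, and 6.28e-04 with an estimated correlation). Its genes with the lowest p were Serpinf1 (4.51), Ccng1 (-3.05) and Dcxr (-3.54). The X chromosome was higher (median 0.29, 75 of 378 higher and 11 lower, and 89 and 14 when adjusted over the list alone, adjusted p = 1.82e-04), led by Ctps2 (1.62), Lamp2 (1.80) and Col4a5 (adjusted p = 1.26e-05). Its adjusted p was 0.184 with an estimated correlation, and the call was lost without haploid EpiSC-2 (adjusted p = 0.634). Chromosome 13 was lower (-0.26, adjusted p = 0.00312, and adjusted p = 0.428 with an estimated correlation), with Ocln (-3.78), Tgfbi (5.93) and Gas1 (3.12) at the lowest p. Chromosome 6 was higher (0.17, adjusted p = 0.0206, and adjusted p = 0.414 with an estimated correlation), with Col1a2, Rps4l and Mest at the lowest p. The shift of chromosome 13 was -0.48 in haploid EpiSC-1 and -0.07 in haploid EpiSC-2, and that of chromosome 6 was 0.31 and 0.01.

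**Figure D4:**
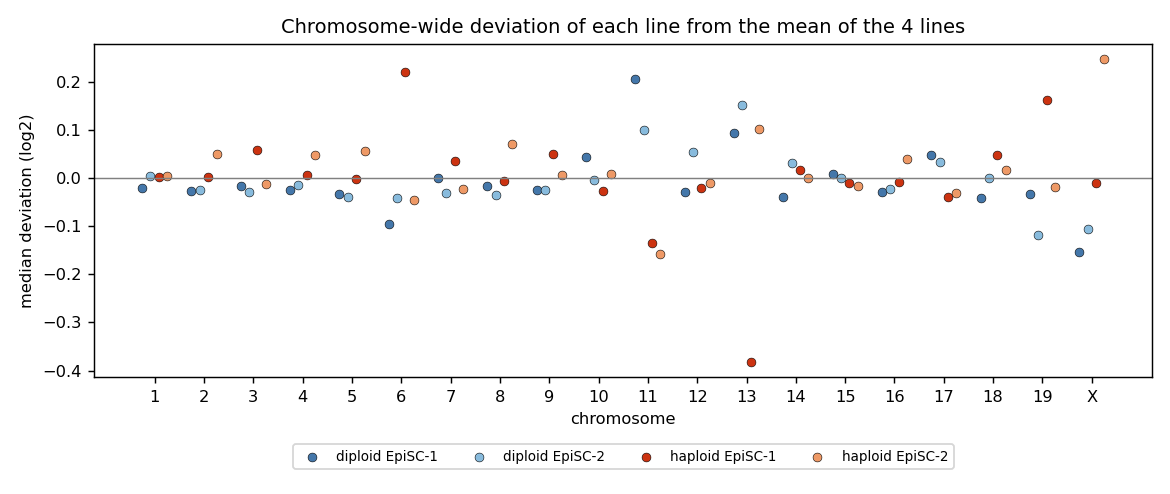
Median deviation (vertical axis, log2) of the genes of each chromosome (horizontal axis) in each line from the mean of the 4 lines, relative to all autosomal genes, with 1 point per line. Both haploid lines lie below both diploid lines on chromosome 11 (-0.13 and -0.16 against 0.21 and 0.10), haploid EpiSC-1 lies apart on chromosome 13 (-0.38), and haploid EpiSC-2 is highest on X (0.25).

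The second comparison set the haploid lines against each other. Several regulators of the primed epiblast and of endoderm were far higher in haploid EpiSC-2 than in haploid EpiSC-1, while the primed epiblast list as a whole had a median difference of 0.46 (13 of 21 genes higher and 3 lower, and 14 and 3 when adjusted over the list alone, adjusted p = 1.15e-04). Otx2, an epiblast transcription factor, was higher by 4.96 ± 0.07 (log2, SE, 3 arrays each, adjusted p = 1.40e-15) and Fgf5, the marker growth factor of the primed epiblast, by 4.86 ± 0.17. In signal, Otx2 was at 74.0 in haploid EpiSC-1 and 2290 in haploid EpiSC-2, against 3962 and 2133 in the diploid lines, and Fgf5 at 86.9 and 2424 against 3621 and 2332. Between the ploidies Otx2 was at -2.82 with overlapping arrays (adjusted p = 0.0403, up to 0.334 over the alternatives) and Fgf5 at -2.69 (adjusted p = 0.062).

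Between the haploid lines 6288 genes passed, 2849 (45.3%) higher and 3439 lower in haploid EpiSC-2, and 237 and 523 of these differed at least 2-fold. Centring on array medians shifted the median of all genes by 0.16 and gave 4184 (65.5%) higher and 2207 lower. The largest increases were Irs4 (6.07), the endoderm factor Sox17 (5.33), Lhx1 (5.17), Spink1 (5.11) and the Nodal antagonist Cer1 (5.02). The largest decreases were Csn3 (-3.58), Smoc2 (-3.27), the matrix gene Thbs2 (-3.15), Olig1 (-2.94) and Camk2n1 (-2.75). Sox2 changed by -0.42, Pou5f1 rose by 0.68 and Nanog by 0.49. With so many genes past the threshold, replicates measure the spread within a line and not the spread between haploid lines in general.

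Chromosome 13 was higher in haploid EpiSC-2 (median 0.41, 243 of 391 genes higher and 20 lower, adjusted p = 5.99e-19), as was X (0.25, adjusted p = 1.91e-08). Chromosomes 6 (-0.31, adjusted p = 1.30e-07) and 19 (-0.25, adjusted p = 0.00103) were lower. All 4 passed with an estimated correlation too. With that correlation chromosomes 3 (-0.10, adjusted p = 0.00576) and 8 (0.03, adjusted p = 0.00751) passed as well. In 7 of 10 splits of the 6 haploid arrays, the real one included, 4 chromosomes passed the preset test. On chromosome 13 the lowest p belonged to Emb (2.15), the activin-binding Fst (3.07) and Eef1e1 (1.14). On X they were Amot (1.78), Bex2 (1.27) and Xist (3.97), and on chromosome 6 the stress gene Gadd45a (-1.71), Bhlhe40 (-1.39) and the histone demethylase gene Kdm3a (-1.04). Those of chromosome 19 were Pga5 (4.44), the retinoic acid hydroxylase gene Cyp26a1 (2.15) and Cep55 (-1.20).

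The third comparison set the diploid lines against each other. Xist, the RNA that coats the inactive X chromosome of female cells, was higher in diploid EpiSC-2 by 7.67 ± 0.12 (log2, SE, 3 arrays each, adjusted p = 1.74e-15). Its signal was 56.8 in diploid EpiSC-1 and 11558 in diploid EpiSC-2. The Y-linked gene Uty, under the signal filter over all arrays, showed the opposite on its brightest probe set, with signals of 232 ± 10.3 and 23.3 ± 3.82 (SD, n = 3). Y-linked Kdm5d was at 36.8 and 35.2 on its brightest probe set and differed on 1 of its 3 probe sets, at 792 and 3.44. In the haploid lines Xist was at 39.5 and 616, Uty at 20.6 and 13.2, and Eif2s3y at 4.47 and 5.38.

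Of 11105 genes, 6196 passed, 2928 higher and 3268 lower in diploid EpiSC-2, with 489 and 264 of these at least 2-fold. After Xist, the largest increases were Zfp182 (6.50), the neurofilament gene Nefm (6.20), Rcan2 (5.47) and Acot1 (4.85). The largest decreases were the lysosomal hexosaminidase gene Hexa (-7.16), Fundc2 (-6.92), Insig1 (-5.50), Fbxw17 (-4.99) and Gpx7 (-4.23). Nanog changed by -1.14, Otx2 by -0.89, Fgf5 by -0.64, Dnmt3b by -0.59 and Klf4 by 1.18. With limma's cameraPR 0 chromosomes passed, and 1 had an unadjusted p under 0.05. This was chromosome 11 (median -0.12, unadjusted p = 0.00805, adjusted p = 0.161), and with quantile normalization 1 chromosome passed.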

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

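The tests of feeder cells, of a paternal genome, of the Meg3 locus, of strain variants, of the ratio of X to autosomes and of the spread between chromosomes were chosen after the results they address were seen, as were the list tests between the haploid lines and the restriction of single genes to differences of at least 2-fold. The splits of the arrays, the strain test and the test of expression level were chosen before.

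Single genes were taken up where the haploid lines differed in the direct test between them. The differences of haploid EpiSC-2 minus haploid EpiSC-1 were 4.96 for Otx2, 4.86 for Fgf5, 1.05 for Dnmt3b, 3.97 for Xist and 2.64 for Grb10. They were -1.82 for Megf10, -2.94 for Olig1, -1.499 for Eda2r and -1.25 for Dcxr. No test of single outlying arrays was run on groups of 3 arrays.

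Of the gene lists, 15 differed between the haploid lines. Definitive endoderm genes had a median difference of 1.92 (8 of 11 higher and 1 lower, adjusted p = 4.42e-04), primitive streak and mesoderm genes of 1.19, core pluripotency genes of 0.50, Nodal and Activin targets of 0.49, primed epiblast genes of 0.46 and X-inactivation genes of 0.45. Cholesterol synthesis genes stood at 0.25, G1/S and DNA replication genes at 0.15, ribosomal protein genes at 0.0506 and oxidative phosphorylation genes at 0.0321. Hypoxia genes were at -1.07 (1 of 19 higher and 16 lower, also when adjusted over the list alone, adjusted p = 2.94e-08), BMP targets at -0.65, interferon-stimulated genes at -0.56, glycolysis genes at -0.34 and p53 targets at -0.16. With an estimated correlation 9 lists passed. Those lost were Nodal and Activin targets (adjusted p = 0.0970), BMP targets (0.111), glycolysis (0.144), oxidative phosphorylation (0.342), ribosomal proteins (0.550) and p53 targets (0.0513). Whole chromosomes differed by 0.41 for chromosome 13, 0.25 for X, -0.31 for chromosome 6 and -0.25 for chromosome 19.

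In 100 splits of the 12 arrays, each 6 against 6 with the real one included, the line correlation of the other splits was estimated on 1500 genes. Only the real split, 1 of 100, gave 1913 genes (highest other 2), 13 lists (highest other 3) or 4 chromosomes (highest other 2), but these splits divide lines whose replicates are alike, which keeps their calls near 0, so they do not decide on chance. Whole lines can be paired in 3 ways, too few for a share under 0.05: 1 of 3 gave 1913 genes and the highest other 15. The 10 splits of 6 arrays are also too few for a share under 0.05. For the haploid lines 1 of 10 gave 6288 genes (highest other 0) and 7 of 10 gave 4 chromosomes (highest other 4). The written prediction for chance was another split with as many calls, and the chromosomes met it. The other splits still set unequal numbers of arrays of the 2 lines against each other, so this does not decide on chance. For the diploid lines 1 of 10 gave 6196 genes (highest other 1) and 10 of 10 gave 0 chromosomes (highest other 0). Any split reaches a count of 0.

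Fibroblast markers were higher in both haploid lines, and feeder fibroblasts, which the labels do not mention, may have contributed RNA. If feeders carry Xist and Eif2s3y at the level of the diploid line of that sex, these transcripts allow a feeder share of 0.491% ± 0.243 (SD) in haploid EpiSC-1, under the 2.05% that the median risen marker needs, with 19 of 21 genes needing more (up to 22.9% for Fn1). The needs in both lines assume that feeders carry every marker at 37926.6, the highest signal on any array, so a lower feeder level would raise them. Neither feeder profile was measured, so the comparison of share and need excludes nothing. In haploid EpiSC-2 the share of 5.51% ± 0.378 exceeded the need of the median gene (1.83%) and of the upper quartile (3.38%). It fell short for 5 of 21 genes (up to 32.8% for Acta2). Feeders in haploid EpiSC-2 cannot be told apart from expression by the line, whose Xist may be its own. In haploid EpiSC-1 the sex transcripts gave no sign of feeder RNA, but feeders are not excluded. The criterion, that every risen gene be covered, was set after these values were seen. It replaced 2 looser ones, the latter of which haploid EpiSC-2 met. With 0 lines of a strain measured at both ploidies, strain and ploidy cannot be told apart.

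Paternally expressed genes were higher and several maternally expressed genes lower in haploid cells, and a single paternal genome is a candidate explanation. The paternal list lay above the maternal list in each of the 4 pairs of a haploid with a diploid line, by 0.97 at the least and 1.29 at the most, but this restates the pattern and does not test the explanation. At the maternally expressed Meg3, Rian and Mirg it predicted a mean fall of at least 3 log2 units, and the mean was -0.28 (SD 0.13). The predicted fall was thus absent at that locus. The prediction holds only if imprinting is kept there, which was not tested. Its bar was set after the values were seen and the SD is over the 3 genes, so the result does not decide on a paternal genome. Strain variants under single probe sets stay open. Of 19 other probe sets of the changed genes 16 (84.2%) had the same sign, which met the bar set for this test. Only 14 (73.7%) had it by more than the SD between replicates, which missed the same bar. This stricter count was not part of the written prediction, and several of the probe sets belong to the same gene. A difference of imprinting between the strains or lines stays open and was not tested.

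X-linked genes were higher in haploid cells in the preset test, but not with an estimated correlation (adjusted p = 0.184) or without haploid EpiSC-2 (adjusted p = 0.634), and a higher ratio of X to autosomes may underlie this. X lay above the autosomal median in each of the 4 pairs of lines, by 0.0799 at the least and 0.43 at the most, but this restates the pattern and leaves the explanation untested. The expression level of X-linked genes is argued against, since the central range of the medians of 10000 autosomal lists matched on signal reached up to 0.0398, against 0.29 for X. The spread of whole chromosomes between lines stays open, since chromosome 11 shifted by -0.30, which at 0.30 in size exceeds X. Sex chromosomes differed between the diploid lines as well, and their part was not tested.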

How the results depend on the processing

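The list tests between the haploid lines were added after the data had been seen; the other alternatives were chosen before. The haploid against diploid count depended most on how lines were treated. It was 8180 genes without the line block and 325 with line means, 2 against 2, where among the tracked genes 62 calls were lost and 71 kept. Leaving out a line meant a fit without the block, with 7794 (without diploid EpiSC-1), 7903 (without diploid EpiSC-2), 7277 (without haploid EpiSC-1) and 8142 genes (without haploid EpiSC-2). It was 3291 without a signal filter, 980 with a stricter signal filter, 3562 over all probe sets and 968 at 2-fold or more, where the number tested or the threshold differs by construction. Leaving out single arrays gave 1728 to 1811 genes, 13 lists and 4 chromosomes. With an estimated correlation 7 lists and 1 chromosome passed. Quantile normalization left 9 lists, without core pluripotency, G2/M, oxidative phosphorylation and ribosomal protein genes. Without a signal filter 2 chromosomes passed, and without haploid EpiSC-1 also 2. The lists of fibroblast, mesenchymal, epithelial and paternally expressed genes and of BMP targets, and chromosome 11, kept their direction and call in all 28 alternatives, while core pluripotency kept its call in 23 of 28. Between haploid lines the counts were 10756 over all probe sets, 760 at 2-fold or more and 5689 to 6354 without single arrays, with 9 lists under an estimated correlation and 13 to 15 without single arrays, and 4 chromosomes without single arrays. Between diploid lines they were 11628, 753 and 5590 to 6202, with 1 chromosome under quantile normalization and 0 without single arrays. Quantile normalization reversed the medians of oxidative phosphorylation genes (-0.0578, adjusted p = 0.944) and ribosomal protein genes (-0.00502, adjusted p = 0.771) between the haploid lines. Where no construction is named, the cause was not tested. With the replicate block 1651 genes, 13 lists and 4 chromosomes passed between the ploidies, and replicate numbers do not pair samples, since deviations of arrays with the same number correlated at -0.0466 to 0.0765. Signals near the background limit the folds, as for Pmaip1.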

Other observations

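The genes below, apart from Hoxa9, were chosen after their values were seen. No explanation was tested for the Hox genes. Of the genes of the Hox clusters, 10 were tested and 10 had higher means in haploid than in diploid cells, 7 of them past the threshold. They were Hoxa9 (6.46), Hoxa10 (6.05, adjusted p = 0.0192), Hoxb9 (5.33), Hoxd9 (4.93 ± 0.49, adjusted p = 6.23e-06), Hoxa11 (3.34, adjusted p = 0.0451), Hoxd13 (2.98) and Hoxb3 (2.38). Hoxb2 (adjusted p = 0.0518), Hoxd8 (adjusted p = 0.110) and Hoxa5 (adjusted p = 0.498) did not pass, and the call of Hoxa11 was lost under several alternatives. All 10 were lower in haploid EpiSC-2 than in haploid EpiSC-1, 7 of them past the threshold. Mean signals of Hoxa10 were 13.2 and 18.7 in the diploid lines, 1968 in haploid EpiSC-1 and 318 in haploid EpiSC-2. The signal filter was on the mean over all arrays, so Hox genes low in diploid cells were tested only if high in haploid cells. This favours the count of 10 of 10 higher in haploid cells, and Hox genes under the filter were not counted.

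Among paternally expressed transcripts of imprinted loci, Kcnq1ot1 rose by 5.64 (adjusted p = 0.0156), Airn by 4.89 (adjusted p = 0.00943, with its other tested probe set at 2.19) and Peg12 by 3.64 (adjusted p = 7.81e-04). Meg3 was at -0.28 (adjusted p = 0.0528) and Mirg at -0.16 (adjusted p = 0.714).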
